A study of Mus musculus with 3 samples.

How the data were processed

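Single-cell RNA libraries were made from liver parenchymal cells of mice, prepared by collagenase perfusion and low-speed spins, with droplet barcoding on the 10x Chromium system and sequencing on an MGI instrument, per the labels' protocols. There were 3 libraries, 1 per group: control, LPS for 3 hours and LPS for 12 hours, both LPS groups after poly(I:C) priming. Groups were taken from the sample labels. The deposited tables hold whole-number UMI counts per gene and barcode, not normalised. Cell Ranger (version not given), FastQC 0.11.7 and the genome build mm9 are named in the submitters' processing notes, with no role or order; no coordinates are printed here. Whether the authors removed doublets or pooled mice is not given in the sources used here.

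The deposited counts held 24270 barcodes and 16407 gene symbols, of which 172 had no count in any library and 16215 were found in the reference gene names. The tables had been filtered before deposit, as the values show: the highest mitochondrial share of a barcode was 20.0%, 19.9% and 20.0%, and the lowest UMI number 4963, 6002 and 3686, for control, 3 hours and 12 hours. The filters planned here (at least 500 UMIs, at least 250 genes and at most 40% mitochondrially encoded UMIs, or at least 1000, 500 and at most 20%) therefore removed no barcode and test nothing. Depth sets the precision: 3 counts correspond to 0.0709 CPM in control, 0.0243 CPM at 3 hours and 0.0208 CPM at 12 hours.

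Cells were clustered within each library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled (at most 10 units from the mean) and reduced to 30 principal components, and a graph of 15 neighbours was partitioned by the Leiden method with 2 iterations in scanpy 1.11.5 with igraph 0.11.9. Clusters were named from markers of 12 classes, and a cluster stayed unnamed if its 10 leading genes held more markers of another class than of hepatocytes. The resolution of 0.1 was chosen after the partition at a resolution of 1 had been seen, because the latter left 21.6%, 17.5% and 34.4% of cells in unnamed clusters (control, 3 hours, 12 hours), so the share of 100% reported for the coarse resolution depends on that choice. The definition of finer clusters with endothelial or blood cell markers, which does not count monocyte markers, was altered 3 times before any result without them had been computed, and a definition that counts them was added afterwards. No class other than hepatocyte-like cells was named at the coarse resolution, so the planned comparison of other classes was not made. Finer clusters with endothelial markers, of 144 cells at 3 hours and 171 at 12 hours, stayed unnamed and were not compared. Scrublet called 10, 3 and 0 doublets at an expected rate of 6%. These calls were so few that they were not relied on, and doublets may remain in the sums. Leaving out cells with UMIs of more than 1 endothelial, macrophage, neutrophil or lymphocyte marker gene removed 1.93%, 5.76% and 6.01% of cells.

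UMIs were summed over the hepatocyte-like cells of a library and divided by the total (CPM). Levels have exact Poisson 95% intervals, ratios of CPM exact conditional 95% intervals and shares exact Clopper-Pearson 95% intervals, all of which cover counting error only. Log2 ratios used a pseudocount of 1 CPM, which understates the difference of low genes, and folds used none. A fold against a library with no count was computed against the level of 3 counts in that library. With 1 library per group no p-value was computed, and the number of differing genes is not given.

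The 28 gene lists were acute phase proteins, constitutive plasma proteins lowered in the acute phase, interferon-stimulated genes, NF-kB targets and cytokine signalling, antigen presentation by MHC class I, complement, coagulation and fibrinolysis, drug and xenobiotic metabolism, bile acid synthesis and transport, fatty acid oxidation and ketogenesis, fatty acid synthesis and lipid storage, cholesterol synthesis and uptake, gluconeogenesis with glycolysis and glycogen, urea cycle and amino acid catabolism, nuclear-encoded oxidative phosphorylation, the unfolded protein response, heat shock and immediate early genes, antioxidant genes, iron handling, inflammasome with necroptosis and apoptosis, cell cycle, growth hormone axis and male-biased genes, liver transcription factors, circadian clock, glucocorticoid targets, pericentral genes, periportal genes and mitochondrially encoded transcripts. Lists overlap: 30 of their 657 genes are in more than 1 list. A member was measured if it reached 10 CPM in 1 of the compared libraries. Each list has its median log2 ratio, an order-statistic 95% interval over members where their number allows one, the number of members at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

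Lists, markers, the rule for named genes, the pairs of libraries and the first set of alternatives were fixed before the data were examined. By that rule, each pair gives the 10 highest and 10 lowest log2 ratios, ranked by the limit of the counting interval nearest to no difference, among genes of at least 50 CPM in 1 of the 2 libraries, without mitochondrial, ribosomal protein, haemoglobin, marker and unnamed genes. It adds up to 4 members per list (the 2 highest and 2 lowest of at least 10 CPM) and, in any case, the levels of Glul, Cyp2e1, Cyp2f2, Cyp7a1, Hamp, Alb, Saa1, Cxcl10 and Casp4. Besides the latter, up to 30 were named per pair, in rank order within each list or end, and which lists and ends received a named gene was decided after the values were seen. Members named behind counts of 5 or fewer, single markers of other cell types, leading genes of clusters, and Saa2, Hamp2, Oat and Slc1a2 in the zonation results were also chosen after their values were seen. Results of some single genes are not reported here.

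For zonation, each cell was thinned to 1000 UMIs, with 0 cells left out, and the pericentral and periportal lists were summed per cell. Their Spearman correlation has an approximate 95% interval by Fisher's transformation. Terciles of cells came from the difference of the 2 sums, each divided by its mean, cells within 0.1 of a limit were counted as near it, and levels in a tercile used the UMIs not drawn in the thinning. Shares of cells with a UMI used terciles made without the gene itself. Median of ratios factors were computed with numpy 2.4.6, and TMM factors with edgeR 4.0.16 in R 4.3.3. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used, with random seed 1.

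The first set of alternatives held other scalings (median of ratios, TMM, the total without mitochondrially encoded genes), equal weight of cells, thinning to 1000 UMIs, a pseudocount of 5 CPM, no minimum level, other cell filters, all kept cells, joint clusters, doublets or cells of mixed content left out, and thinning to 500 or 2000 UMIs for zonation. Alternatives chosen after seeing the data were the total without the acute phase, interferon-stimulated and NF-kB lists, cells under 5% mitochondrial share left out, finer clusters with endothelial or blood cell markers left out (not counting monocyte markers, and counting them), control cells led by interferon-stimulated genes left out, members with no count set to 3 counts, and the clusters of the finer resolution.

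The computations were tested on simulated Poisson counts drawn from the real means with 200 genes changed. The draws held no variation between cells or libraries beyond counting error and were scaled by the known totals. They check the arithmetic and not how well the intervals cover differences between real libraries. Intervals held the true ratio for 95.7% of 6405 genes in the simulated 3-hour against control pair, 95.2% of 6531 genes for 12 hours against control and 95.3% of 6252 genes for 12 against 3 hours. In each simulated pair, all genes changed 1.5-fold (68), 2-fold (66) and 4-fold (66) had intervals on the right side of 1, and a list of 20 genes lowered 2-fold had a median of -0.96, -0.96 and -0.95 at percentile 0. An unchanged list of 20 genes lay at percentiles 35.3, 58.9 and 33.1.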

Results

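Transcripts were counted in single cells of the liver parenchyma, a preparation that consists mainly of hepatocytes, from male C57BL/6J mice in a model of endotoxaemia. The control library came from mice injected with saline. The 3-hour library came from mice that first received poly(I:C), a synthetic double-stranded RNA that sets off an antiviral response, and 7 hours afterwards lipopolysaccharide (LPS), the endotoxin of Gram-negative bacteria, which acted for 3 hours. In the 12-hour library LPS acted for 12 hours after the same priming. The labels state 6 mice of 8 weeks of age per group and an overnight fast, and do not say whether the cells of several mice were pooled. Each group is 1 library, so no test between groups was possible, no difference below has a replicate check, and a difference between libraries cannot be separated from variation between mice or cell preparations. Intervals cover counting error only. The control mice received neither poly(I:C) nor LPS, and the poly(I:C)-only group that the labels mention is not analysed here. Differences from control therefore cannot be assigned to LPS or to the priming. The LPS groups may also differ from control in the time since the first injection and in the time of day, which the labels do not give. They differ from each other in the time since poly(I:C) as well as since LPS, and possibly in the time of day.

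The control library held 3153 barcodes and 42334663 UMIs, with a median of 12766 UMIs and 2994 genes per barcode. The 3-hour library held 10412 barcodes and 123607608 UMIs, with medians of 11107 UMIs and 2642 genes. For the 12-hour library these values were 10705 barcodes, 144304030 UMIs, 13046 UMIs and 2855 genes. A gene with no count is limited to 0.0709 counts-per-million (CPM) in control, 0.0243 CPM in the 3-hour library and 0.0208 CPM in the 12-hour library, the level of 3 counts. Mitochondrially encoded transcripts took 14.2% of all UMIs in control, 8.76% in the 3-hour library and 7.21% in the 12-hour library. The 32 acute phase genes took 2.63%, 11.7% and 23.3% in the same order.

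At the coarse clustering resolution all cells of the 3 libraries fell into hepatocyte-like clusters (100% each, with exact lower limits of 99.9%, 100.0% and 100.0%), and each of the 11 hepatocyte markers was detected in every one of them. The same held for every finer cluster, including a control cluster of 20 cells led by endothelial genes such as Clec4g and Kdr. Such detection in summed cells therefore does not separate hepatocytes from other cells. Some of the coarse clusters, made within each library, had a low mitochondrial share. A cluster led by Malat1, a nuclear non-coding RNA, held 9.29% of control cells, 8.56% at 3 hours and 0.943% at 12 hours, with a median mitochondrial share of 3.75%, 2.44% and 1.13%. A cluster with Psmb5, Ubb and Sds among its leading genes held 24.7% of control cells and 7.18% at 3 hours, at medians of 3.01% and 1.73%, and the 12-hour library formed no such cluster. All these cells are in the sums. At the finer resolution the share in clusters that kept the name was 78.4% in control, 82.5% at 3 hours and 65.6% at 12 hours. The remaining cells lay in clusters with at least 1 marker of another class among their 10 leading genes. Most of these were periportal clusters led by genes such as Ctsc and Cyp2f2 together with Spp1, a bile duct marker (503 cells in control, 1683 at 3 hours, and clusters of 1384 and 1300 cells at 12 hours), and at 12 hours a cluster of 826 cells carried Plac8, a monocyte marker. Finer clusters with endothelial or blood cell markers other than those of monocytes held 5.65% of control cells, 1.38% of 3-hour cells and 1.60% of 12-hour cells, and with the Plac8 cluster the last of these shares was 9.31%. The control share was mostly a cluster of 158 cells (5.01%) with the haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt among its leading genes. These genes had only 68, 23 and 16 UMIs in the whole control library. The control cluster led by endothelial genes held 20 cells (0.634%). UMIs were summed over all hepatocyte-like cells of the coarse resolution for what follows.

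Markers of other cell types were low in these sums, and several differed between libraries. Endothelial markers summed to 26.6 CPM in control, 8.38 CPM at 3 hours and 16.8 CPM at 12 hours, of which Stab2 gave 5.46, 3.11 and 11.5 CPM. Monocyte markers summed to 2.83, 18.4 and 45.1 CPM, of which Plac8 alone gave 2.62, 17.4 and 44.7 CPM. Neutrophil markers gave 0.803, 12.3 and 12.6 CPM, of which Hdc gave 0.661, 6.91 and 2.25 CPM and Il1r2 0.0472, 0.655 and 6.13 CPM. T or NK cell markers gave 1.13, 31.7 and 4.19 CPM, of which the chemokine gene Ccl5 gave 0.543, 31.6 and 4.02 CPM. Macrophage markers gave 1.02 CPM in control (0.735 to 1.37), 1.37 CPM at 3 hours (1.17 to 1.59) and 1.83 CPM at 12 hours (1.62 to 2.06), mostly from Cd68 (0.968, 0.833 and 1.42 CPM). B cell markers gave 1.02, 0.785 and 1.199 CPM, and platelet markers 1.77, 1.01 and 1.03 CPM. Dendritic cell markers gave 135, 191 and 215 CPM, almost entirely from Cst3, which hepatocytes also express. Stellate cell markers gave 2.74, 1.24 and 1.08 CPM, and erythroid markers 55.7, 36.8 and 19.7 CPM, nearly all of it from Alas2, a haem synthesis gene (53.0, 36.7 and 19.1 CPM), while the haemoglobin gene Hbb-bs gave 1.61, 0.0162 and 0.333 CPM. Cholangiocyte markers were 17.4 CPM in control, 112 CPM at 3 hours and 135 CPM at 12 hours, most of it Sox9, a transcription factor of bile duct and periportal cells (10.6, 97.1 and 108 CPM).

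The median log2 ratio over all genes of at least 10 CPM was -0.26 for the 3-hour library against control, -0.13 for the 12-hour library against control and 0.098 for the 12-hour against the 3-hour library. Median of ratios scaling gave 0.11, 0.028 and -0.10, TMM scaling 0.14, 0.094 and -0.066, the total without mitochondrially encoded genes -0.36, -0.25 and 0.078, and the total without the acute phase, interferon-stimulated and NF-kB lists -0.052, 0.24 and 0.27. A list's value "relative to all genes" is its median less the first of these medians. The other 4 scalings are named beside a list only where they turn its direction, move the split of members by over 10 percentage points, or move a count of members by over 1.5 times or to or from 0.

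The first comparison sets hepatocyte transcripts of primed mice 3 hours after LPS against those of unprimed control mice. In the 3-hour library, 46 of 46 measured interferon-stimulated genes and 31 of 34 NF-kB targets and cytokine signalling genes were at least 2-fold higher than in control. Of the acute phase genes, most of which encode plasma proteins that the liver secretes in inflammation, 27 of 30 were at least 2-fold higher. At least 2-fold lower were 13 of 27 carbohydrate genes, 10 of 21 bile acid genes, 11 of 22 fatty acid synthesis genes, 11 of 27 fatty acid oxidation genes, 12 of 28 urea cycle and amino acid genes and 12 of 22 liver transcription factors. With median of ratios scaling these counts were 8, 7, 6, 9, 3 and 9. Cxcl10, an interferon-induced chemokine, stood at 5136 CPM against 7.13 CPM in control, and G6pc, the enzyme that releases free glucose from glucose 6-phosphate, at 2.22 CPM against 589 CPM.

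Interferon-stimulated genes had a median log2 ratio of 4.59 (interval 3.75 to 5.96), or 4.85 relative to all genes, at percentile 100 of random lists. Ifit2, an antiviral protein that binds RNA, was 781-fold higher (583 to 1070). Gbp5, a guanylate-binding protein of the response to intracellular bacteria, had 12419 UMIs in the 3-hour library and none in control and was at least 1418-fold higher, against the level of 3 counts. NF-kB targets had a median of 3.87 (2.58 to 5.01), or 4.13 relative to all genes, also at percentile 100, and Il6ra was the 1 member at least 2-fold lower. Ccl2, which recruits monocytes, stood at 1639 CPM against 0.0472 CPM, a ratio of 34684 (9601 to 286396) that rests on 2 UMIs in control. Tlr2, a receptor for bacterial lipoproteins, was 1408-fold higher (683 to 3503) and Cxcl10 720-fold (643 to 809). Ccrl2, a receptor that binds the attractant chemerin, was 844-fold higher (503 to 1545). In the genes of antigen presentation by MHC class I, 15 of 18 members were at least 2-fold higher, with a median of 2.15 (1.45 to 2.91), or 2.41 relative to all genes. H2-Q6, a non-classical class I gene whose reads can be shared with its close relatives, was 24.0-fold higher (21.6 to 26.7).

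Acute phase genes had a median of 2.46 (1.93 to 3.39), or 2.72 relative to all genes, at percentile 100. Lcn2, which withholds iron from bacteria by binding their siderophores, was 265-fold higher (243 to 291), and Cd14, a co-receptor for LPS, 474-fold (271 to 917). Saa1, a serum amyloid A gene, was 91.7-fold higher (89.0 to 94.5), although reads can be shared with Saa2. Hamp, which encodes the iron hormone hepcidin, was 3.91-fold higher (3.89 to 3.94). The 17 constitutive plasma proteins, listed beforehand as lowered in the acute phase, had a median of -0.15 (-0.25 to 0.31), 0.11 relative to all genes. No member differed by 2-fold. The direction of that median turned to 0.20 with median of ratios scaling, 0.23 with TMM and 0.051 without the 3 immune lists, and 1, 2 and 1 members were then at least 2-fold higher. Alb, which encodes albumin, had a log2 ratio of -0.32, which turned to 0.033 with median of ratios scaling and 0.063 with TMM.

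Complement genes had a median of 0.23 (-0.21 to 0.70), 0.49 relative to all genes, and the 3 of 19 members at least 2-fold higher were Mbl1, Mbl2 and Serping1, with 5 higher under median of ratios or TMM scaling. Mbl2, a mannose-binding lectin that starts complement activation on microbes, was 2.51-fold higher (2.46 to 2.56). Coagulation genes had a median of -0.13 (-0.48 to 0.48), 0.13 relative to all genes, which turned to 0.22 with median of ratios scaling, 0.25 with TMM and 0.072 without the immune lists. In a list of 19, 3 members, Cpb2 and F3 among them, were at least 2-fold higher and Klkb1 was lower, and with these 3 scalings the split was 3 higher and 0 lower. The list of inflammasome, necroptosis and apoptosis genes had 10 of 19 members at least 2-fold higher and none lower, and 8 higher and 1 lower without mitochondrially encoded genes in the total. Its median was 1.05 (0.60 to 1.75), or 1.31 relative to all genes, at percentile 100. Mlkl, the executioner of necroptosis, was 52.5-fold higher (38.7 to 73.2). Casp4, the gene of the LPS-sensing caspase-11, stood at 3.03 CPM against 0.213 CPM, a ratio of 14.2 (7.42 to 31.4) from 9 UMIs in control.

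In the list of gluconeogenesis, glycolysis and glycogen, 13 of 27 members were at least 2-fold lower, or 8 with median of ratios or TMM scaling, and Igfbp1, Ldha and Pfkfb3 were higher, with a median of -0.86 (-1.54 to -0.39), or -0.60 relative to all genes, at percentile 0. G6pc was lower by a factor of 265 (235 to 299), and Pck1, which makes phosphoenolpyruvate for gluconeogenesis, by a factor of 9.10 (8.99 to 9.22). Pfkfb3, which drives glycolysis through fructose 2,6-bisphosphate, was 33.7-fold higher (29.9 to 38.2). Fatty acid synthesis and lipid storage had a median of -0.97 (-1.38 to -0.32), or -0.71 relative to all genes, with 11 of 22 members lower and Cidec higher. With median of ratios, TMM or the total without the immune lists, 6 were lower. G0s2, an inhibitor of the triglyceride lipase ATGL, was lower by a factor of 1561 (1181 to 2111). Lpin2, a phosphatidate phosphatase outside the list, was lower by a factor of 14.7 (14.1 to 15.3). Fatty acid oxidation and ketogenesis had 11 of 27 members lower and none higher, with a median of -0.80 (-1.62 to -0.60), or -0.54 relative to all genes. Pdk4, which holds back pyruvate oxidation, was lower by a factor of 14.2 (11.4 to 17.8).

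Bile acid synthesis and transport had 10 of 21 members at least 2-fold lower and Cyp7b1 higher, or none higher without mitochondrially encoded genes in the total, with a median of -0.87 (-1.75 to -0.51), or -0.61 relative to all genes, at percentile 0.07. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lower by a factor of 72.5 (63.8 to 82.7), and Nr0b2, the nuclear receptor SHP, by a factor of 25.4 (21.0 to 31.0). Urea cycle and amino acid catabolism had 12 of 28 members lower and none higher, with a median of -0.90 (-1.16 to -0.79), or -0.64 relative to all genes. Only 3 were lower with median of ratios or TMM scaling and 7 without the immune lists. Prodh, the first enzyme of proline breakdown, was lower by a factor of 3.43 (3.31 to 3.54). Drug metabolism genes had a median of -0.40 (-0.80 to -0.26), or -0.14 relative to all genes, at percentile 9.54. Of its 37 measured members 8 were lower and 0 higher, and 6 lower and 1 higher with median of ratios or TMM scaling. Cyp2a5, a coumarin hydroxylase, was lower by a factor of 5.13 (4.9995 to 5.27), and Cyp2e1, which oxidises ethanol and paracetamol, by a factor of 2.22 (2.20 to 2.23). Cholesterol synthesis and uptake had a median of 0.37 (-0.060 to 0.90), 0.63 relative to all genes, with 4 members higher, Sqle, Idi1 and Mvd among them, and 1 lower among 22. That split of 4 and 1 became 8 and 0 with median of ratios or TMM scaling, 8 and 1 without the immune lists and 3 and 3 without mitochondrially encoded genes. Nuclear-encoded oxidative phosphorylation genes had a median of -0.22 (-0.46 to -0.097), 0.037 relative to all genes, which turned to 0.13 with median of ratios and 0.16 with TMM scaling. None of its 33 members differed by 2-fold. The 13 mitochondrially encoded transcripts had a median of -0.73 (-1.04 to -0.57), or -0.47 relative to all genes, and mt-Nd3, mt-Nd6 and mt-Cytb were at least 2-fold lower, but none with median of ratios or TMM scaling, 1 without the immune lists and 5 without mitochondrially encoded genes in the total.

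Liver transcription factors and nuclear receptors had 12 of 22 members at least 2-fold lower and 0 higher, against 9 lower and 1 higher with median of ratios scaling, 8 and 1 with TMM and 11 and 1 without the immune lists, and a median of -1.18 (-1.74 to -0.53), or -0.92 relative to all genes, at percentile 0. Klf15, a regulator of gluconeogenesis and amino acid breakdown, was lower by a factor of 14.2 (13.4 to 15.1), and Onecut1, a factor of hepatocyte differentiation, by 15.0 (12.7 to 17.8). Circadian clock genes had 11 of 16 members lower and Bhlhe41 higher, with a median of -1.40 (-2.0004 to -0.22), or -1.14 relative to all genes. Outside the lists, Usp2, a deubiquitinase with a daily rhythm in liver, was lower by a factor of 34.9 (30.3 to 40.3). Glucocorticoid targets had a median of -0.90 (-1.71 to 1.51), or -0.64 relative to all genes, with Fkbp5, Tsc22d3, Klf9, Per1 and Dusp1 lower and Cdkn1a, Lcn2 and Gadd45b higher among 12. The split of 5 lower and 3 higher was 3 and 3 with median of ratios or TMM scaling. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was lower by a factor of 7.53 (7.15 to 7.92). Growth hormone axis and male-biased genes had a median of -0.33 (-0.996 to 1.29), -0.073 relative to all genes, which turned to 0.017 with median of ratios scaling, 0.046 with TMM and 0.085 without cells of low mitochondrial share. Of its 19 members 7 were higher, mostly major urinary protein genes whose reads can be shared, and Elovl3, Hsd3b5, Igfals and Keg1 were lower. That split of 7 and 4 was 8 and 2 with median of ratios or TMM scaling and 7 and 2 without the immune lists.

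Heat shock and immediate early genes had 8 of 19 members higher and Dusp1 lower, with a median of 0.84 (-0.020 to 1.80), or 1.10 relative to all genes, at percentile 100. Unfolded protein response genes had a median of 0.42 (0.0017 to 0.91), or 0.68 relative to all genes, with Hspa5, Ddit3, Xbp1, Creld2 and Manf higher and Herpud1 lower among 23. The 5 higher became 8 with median of ratios and 9 with TMM scaling. Creld2, a protein of the endoplasmic reticulum, was 3.66-fold higher (3.39 to 3.95), and Herpud1, which acts in degradation of misfolded proteins, was lower by a factor of 4.27 (4.18 to 4.36). Antioxidant genes had a median of 0.12 (-0.75 to 0.94), 0.38 relative to all genes, with Hmox1 and Txn1 higher and none of 16 lower. There were 4 higher with median of ratios, 5 with TMM and 4 without the immune lists, and 1 was lower without mitochondrially encoded genes in the total. Hmox1, which breaks down haem, was 27.6-fold higher (24.6 to 31.0). Iron handling genes had a median of -0.87 (-2.41 to 0.48), or -0.61 relative to all genes. Slc40a1, Hfe2, Smad7, Id1 and Tmprss6 were lower and Slc11a2 higher among 13, and the split of 5 and 1 was 4 and 2 with median of ratios scaling, TMM and the total without immune lists. Cell cycle genes were mostly below the minimum level. Among the 6 measured members Ccnd1, Cdkn1a, Gadd45a and Gadd45b were higher and Rrm2 lower, with a median of 1.57 (-1.97 to 3.64), or 1.83 relative to all genes, which was -0.085 with no minimum level. The split of 4 and 1 was 4 and 0 with TMM and 4 and 2 without mitochondrially encoded genes. Pericentral genes had 7 of 21 members lower, or 4 with median of ratios or TMM scaling, and none higher, with a median of -0.62 (-1.15 to -0.34), or -0.36 relative to all genes. Periportal genes had 9 of 26 lower and 0 higher, with a median of -0.80 (-1.16 to -0.080), or -0.54 relative to all genes, and 4 lower and 1 higher with median of ratios or TMM scaling and 7 lower and 1 higher without the immune lists. Cyp2f2, a periportal cytochrome, had a log2 ratio of -0.37, which turned to 0.014 with TMM scaling and to 0.069 in the cells of the named finer clusters. Glul, the glutamine synthetase of pericentral hepatocytes, had a log2 ratio of 0.081, which turned to -0.0076 without mitochondrially encoded genes in the total, -0.17 without cells of low mitochondrial share and -0.13 in the named finer clusters.

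**Figure D1:**
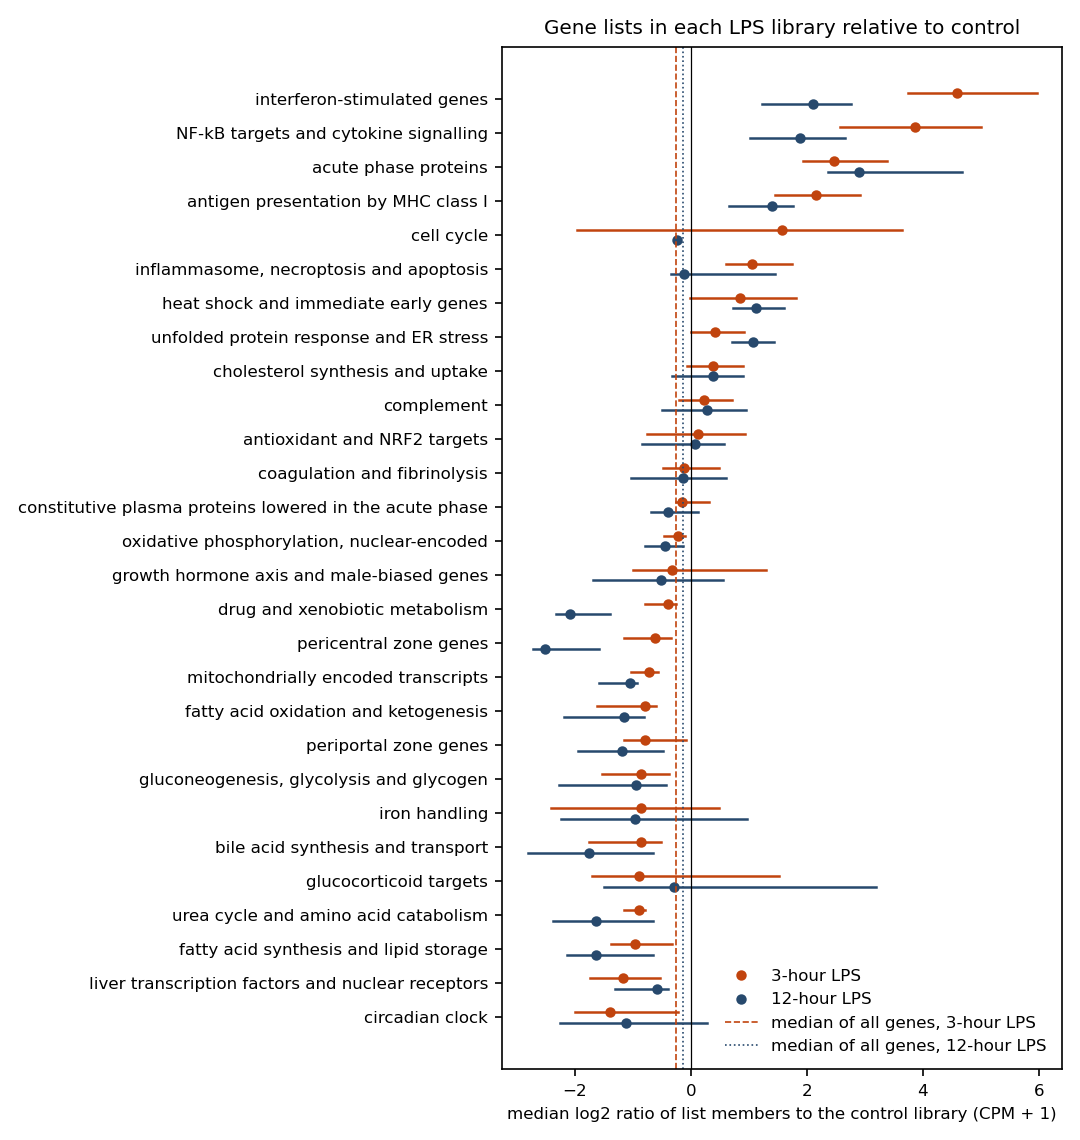
Median log2 ratio of CPM + 1 to the control library for each of the 28 gene lists in the 3-hour and the 12-hour LPS library; points are medians over members, bars their 95% order-statistic intervals over members where one could be formed, and the dashed and dotted lines mark the medians of all genes (-0.26 and -0.13). Interferon-stimulated genes lie at 4.59 and 2.10, acute phase genes at 2.46 and 2.90 and pericentral genes at -0.62 and -2.52.

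The second comparison sets primed mice 12 hours after LPS against the same unprimed control. Acute phase genes took 23.3% of all UMIs in the 12-hour library against 2.63% in control, and 30 of their 32 members were at least 2-fold higher. All 21 measured pericentral genes and 27 of 37 drug metabolism genes were at least 2-fold lower. Interferon-stimulated genes were higher in 28 of 39 members. Saa2, a serum amyloid A gene, reached 31589 CPM against 44.4 CPM in control, and Cyp7a1 stood at 0.0554 CPM, from 8 UMIs, against 144 CPM.

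Acute phase genes had a median of 2.90 (2.36 to 4.68), or 3.04 relative to all genes, at percentile 100. Lcn2 was 1067-fold higher (976 to 1169), Saa3 771-fold (718 to 829), Saa2 712-fold (681 to 745) and Saa1 293-fold (284 to 302). A2m, a protease inhibitor of plasma, had no UMI in control and was at least 1901-fold higher. Reg3b and Reg3g, which encode secreted lectins that kill bacteria, had no UMI in control either and were at least 3242-fold and 1327-fold higher. Hamp was 2.88-fold higher (2.86 to 2.90). The constitutive plasma proteins had a median of -0.39 (-0.69 to 0.11), or -0.26 relative to all genes, at percentile 19.7, with Rbp4 and Serpina6 lower and Apoa4 higher among 17, and the split of 2 and 1 was 2 and 2 with TMM and without the immune lists. Rbp4, the plasma carrier of retinol, was lower by a factor of 3.95 (3.93 to 3.97) and Alb by 1.41 (1.41 to 1.41). Complement genes had a median of 0.28 (-0.49 to 0.96), or 0.42 relative to all genes, with C3, Cfb, Mbl1 and Serping1 higher and C9 lower among 19. The split of 4 and 1 was 5 and 0 with median of ratios or TMM scaling and 6 and 0 without the immune lists. Mbl1, a mannose-binding lectin, was 3.71-fold higher (3.605 to 3.81).

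Interferon-stimulated genes had a median of 2.10 (1.23 to 2.76), or 2.23 relative to all genes, and none of the 39 was 2-fold lower. Gbp2, a guanylate-binding protein, was 187-fold higher (153 to 232). NF-kB targets had 18 of 25 members higher and Il6ra lower, with a median of 1.88 (1.01 to 2.65), or 2.02 relative to all genes. Cxcl9, a chemokine for T cells, stood at 3277 CPM against 21.3 CPM and was 154-fold higher (144 to 164). Ccl2 had a ratio of 537 (149 to 4437), again from 2 control UMIs, and Cxcl10 was 7.03-fold higher (6.27 to 7.92). MHC class I genes had 11 of 16 members higher and none lower, with a median of 1.40 (0.66 to 1.76), or 1.53 relative to all genes. Psmb8, a subunit of the immunoproteasome, was 6.22-fold higher (5.88 to 6.59). The inflammasome, necroptosis and apoptosis list had 6 of 18 members higher and Il18 lower, or 5 and 2 without mitochondrially encoded genes in the total. Its median was -0.12 (-0.34 to 1.46), 0.018 relative to all genes, and turned to 0.034 with median of ratios, 0.094 with TMM, 0.23 without the immune lists, 0.048 with no minimum level and 0.067 in thinned cells. Casp4 had a ratio of 6.39 (3.30 to 14.2).

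Pericentral genes had a median of -2.52 (-2.73 to -1.59), or -2.38 relative to all genes, at percentile 0. Cyp7a1 was lower by a factor of 2593 (1315 to 6008), Cyp2a5 by 43.1 (40.6 to 45.7), Cyp2e1 by 4.68 (4.64 to 4.72) and Glul by 3.13 (3.07 to 3.20). Drug metabolism genes, which share 7 members with that list, had a median of -2.09 (-2.33 to -1.40), or -1.95 relative to all genes, with none higher. Bile acid genes had 13 of 21 members lower and Cyp7b1 higher, or none higher without mitochondrially encoded genes in the total, with a median of -1.75 (-2.81 to -0.66), or -1.62 relative to all genes. Akr1d1, a reductase of bile acid and steroid synthesis, was lower by a factor of 35.3 (33.1 to 37.7). Periportal genes had 14 of 25 members lower and Fbp1, Apoa4 and Sdsl higher, with a median of -1.18 (-1.94 to -0.47), or -1.05 relative to all genes. Sdsl, a relative of serine dehydratase, was 9.37-fold higher (8.74 to 10.0), and Cyp2f2 was lower by a factor of 3.37 (3.32 to 3.43).

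Urea cycle and amino acid genes had 16 of 28 members lower and Sdsl higher, with a median of -1.64 (-2.38 to -0.66), or -1.50 relative to all genes. Fatty acid synthesis genes had 15 of 22 members lower and Plin2 and Cidec, which coat lipid droplets, higher, with a median of -1.64 (-2.14 to -0.65), or -1.50 relative to all genes. Thrsp, a lipogenic factor, was lower by a factor of 25.3 (24.6 to 26.1). Fatty acid oxidation genes had 16 of 27 lower and none higher, with a median of -1.16 (-2.19 to -0.82), or -1.03 relative to all genes. The carbohydrate list had 13 of 27 members lower and Fbp1, Irs2, Ldha and Pfkfb3 higher, with a median of -0.94 (-2.28 to -0.43), or -0.80 relative to all genes. Slc2a2, the glucose transporter of hepatocytes, was lower by a factor of 57.7 (53.3 to 62.4). Among genes in no list, Car3, a carbonic anhydrase abundant in liver, was lower by a factor of 86.8 (84.1 to 89.5), Usp2 by 97.6 (78.9 to 122), the lipid transporter gene Abca8a by 49.9 (42.4 to 59.1) and the steroid dehydrogenase gene Hsd3b3 by 46.6 (41.1 to 53.1). Growth hormone axis and male-biased genes had 8 of 19 members lower and Mup1, Mup7 and Mup21 higher, against 6 and 4 without the immune lists, with a median of -0.52 (-1.69 to 0.55), or -0.38 relative to all genes. Hsd3b5, a steroid dehydrogenase of male liver, was lower by a factor of 160.0 (118 to 222).

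Unfolded protein response genes had 13 of 23 members higher and Herpud1 lower, or none lower without the immune lists, with a median of 1.07 (0.72 to 1.43), or 1.2002 relative to all genes, at percentile 100. Ddit3, the stress factor CHOP, was 9.48-fold higher (8.49 to 10.6), and Manf, a secreted protein of the endoplasmic reticulum, 6.35-fold (6.15 to 6.56). Heat shock and immediate early genes had 12 of 20 members higher and none lower, with a median of 1.12 (0.73 to 1.60), or 1.26 relative to all genes. Liver transcription factors had 9 of 22 members lower, or 5 without the immune lists, and none higher, with a median of -0.59 (-1.32 to -0.40), or -0.46 relative to all genes. Nr1i3, the receptor CAR that controls drug metabolism genes, was lower by a factor of 23.6 (22.2 to 25.2). Circadian clock genes had 8 of 16 members lower and Arntl and Nfil3 higher, with a median of -1.13 (-2.26 to 0.28), or -0.99 relative to all genes. Coagulation genes had a median of -0.14 (-1.03 to 0.61), -0.0025 relative to all genes, which turned to 0.017 with median of ratios, 0.078 with TMM and 0.22 without the immune lists. F5, F13b, Proc, Serpind1 and Klkb1 were lower and 2 members, Cpb2 among them, higher among 18, and the split of 5 and 2 was 4 and 3 with TMM and 3 and 4 without the immune lists. Klkb1, which encodes plasma prekallikrein, was lower by a factor of 13.9 (13.3 to 14.5).

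Cholesterol genes had a median of 0.39 (-0.32 to 0.90), or 0.52 relative to all genes, with Hmgcs1, Sqle, Mvd, Dhcr7 and Msmo1 higher and Stard4 lower among 23. The split of 5 and 1 was 3 and 2 without mitochondrially encoded genes and 9 and 0 without the immune lists. Oxidative phosphorylation genes had a median of -0.44 (-0.78 to -0.14), or -0.31 relative to all genes, with Ndufs1, Sdhb, Sdhc and Atp5a1 lower among 33. These 4 became 8 without mitochondrially encoded genes in the total, 2 with median of ratios, 1 with TMM and none without the immune lists. Mitochondrially encoded transcripts had 8 of 13 members lower, or 5 with median of ratios, TMM or the total without the immune lists, with a median of -1.06 (-1.58 to -0.93), or -0.92 relative to all genes. Antioxidant genes had a median of 0.070 (-0.84 to 0.56), 0.20 relative to all genes, which turned to -0.042 without mitochondrially encoded genes in the total and -0.026 without cells of low mitochondrial share, with Hmox1, Txn1 and Srxn1 higher and Cat, Gclm and Prdx6 lower among 16. Cat, the peroxisomal catalase, was lower by a factor of 9.03 (8.93 to 9.13). Iron handling genes had 7 of 14 members lower and Tfrc and Slc11a2 higher, against 6 and 3 with median of ratios, TMM and the total without immune lists, with a median of -0.97 (-2.24 to 0.96), or -0.83 relative to all genes. Hamp2, a copy of the hepcidin gene, was lower by a factor of 15.4 (14.9 to 15.9), the opposite direction to Hamp, and reads can be shared between the 2 copies. Glucocorticoid targets had a median of -0.30 (-1.50 to 3.18), -0.16 relative to all genes, which turned to 0.049 without the immune lists, with Sgk1, Cdkn1a and Lcn2 higher and Tsc22d3, Klf9 and Gadd45b lower among 12. Cell cycle genes had 5 measured members and a median of -0.23, -0.098 relative to all genes, which turned to 1.22 with TMM scaling, 0.16 without the immune lists. Cdkn1a and Gadd45a were higher and Rrm2 and Gadd45b lower, and the split of 2 and 2 was 2 and 1 with TMM and 1 and 2 without mitochondrially encoded genes.

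The third comparison sets the 12-hour library against the 3-hour library. Interferon-stimulated and NF-kB transcripts were lower at 12 hours, in 38 of 46 and 21 of 33 members, while 15 of 32 acute phase genes were higher still and none was 2-fold lower, or 1 with median of ratios or TMM scaling. Pericentral genes (17 of 19) and drug metabolism genes (23 of 37) were lower than at 3 hours.

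Interferon-stimulated genes had a median of -2.24 (-3.09 to -1.86), or -2.33 relative to all genes, at percentile 0. Cmpk2, a mitochondrial nucleotide kinase, was lower by a factor of 223 (202 to 247), Rsad2, the antiviral enzyme viperin, by 159 (152 to 166) and Ifit1 by 97.7 (94.6 to 101). NF-kB targets had a median of -2.05 (-2.68 to -0.89), or -2.15 relative to all genes, and none was higher. Cxcl10 was lower by a factor of 102 (100.0 to 105), Nos2, the inducible nitric oxide synthase, by 111 (74.6 to 174) and Ccrl2 by 156 (138 to 177). Fam26f, an interferon-induced membrane protein gene, was lower by a factor of 149 (132 to 168). MHC class I genes had 7 of 18 members lower and none higher, with a median of -0.81 (-1.84 to -0.18), or -0.91 relative to all genes, and H2-Q6 was lower by a factor of 6.90 (6.68 to 7.13). The inflammasome list had 9 of 19 members lower, with a median of -0.95 (-1.76 to -0.39), or -1.04 relative to all genes, and Casp4 had a ratio of 0.449 (0.376 to 0.535).

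Acute phase genes had a median of 0.93 (0.45 to 1.30), or 0.83 relative to all genes, at percentile 100. A2m was 18.4-fold higher (17.2 to 19.7) and Saa1 3.20-fold (3.19 to 3.20). Crp, the pentraxin C-reactive protein, was lower by a factor of 1.88 (1.87 to 1.89) and Hamp by 1.36 (1.36 to 1.36), while Alb had a log2 ratio of -0.18. Reg3b was 481-fold higher (373 to 632) and Reg3g 53.6-fold (46.8 to 61.5). Cldn1, a tight junction gene, was 20.8-fold higher (18.8 to 22.96) and Hist2h3c1, a histone gene whose reads can be shared with other histone copies, 20.6-fold (18.4 to 23.02). Unfolded protein response genes had a median of 0.71 (0.48 to 0.84), or 0.61 relative to all genes, with Ddit3, Dnajb9, Sdf2l1 and Manf higher among 23, and 9 of 25 higher without the immune lists. Sdf2l1, a chaperone cofactor, was 2.96-fold higher (2.87 to 3.06). Constitutive plasma proteins had a median of -0.34 (-0.47 to -0.00092), or -0.44 relative to all genes, with Rbp4 and Serpina6 lower and Apoa4 higher among 17. Complement genes had a median of -0.16 (-0.37 to 0.25), or -0.26 relative to all genes, with none of 19 differing by 2-fold and 1 higher without the immune lists. Coagulation genes had a median of -0.19 (-0.77 to 0.090), or -0.29 relative to all genes, with Serpind1, Klkb1 and F3 lower among 19 and 1 also higher without the immune lists. F3, tissue factor, was lower by a factor of 21.7 (18.6 to 25.4).

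Pericentral genes had a median of -1.76 (-2.05 to -1.54), or -1.85 relative to all genes. Glul was lower by a factor of 3.31 (3.26 to 3.37), Cyp2e1 by 2.11 (2.09 to 2.13) and Cyp7a1 by 35.8 (17.9 to 83.7). Drug metabolism genes had a median of -1.23 (-1.76 to -0.93), or -1.33 relative to all genes, and Aox3, an aldehyde oxidase, was lower by a factor of 18.4 (17.0 to 20.03). Periportal genes had 9 of 26 members lower and Arg1, Pck1, Apoa4 and Sdsl higher, with a median of -0.39 (-1.19 to 0.15), or -0.49 relative to all genes, and Cyp2f2 was lower by a factor of 2.62 (2.58 to 2.66). Urea cycle genes had 14 of 28 lower and Arg1, Nags and Sdsl higher, with a median of -0.91 (-1.53 to 0.28), or -1.01 relative to all genes. Sdsl was 7.65-fold higher (7.37 to 7.95). Bile acid genes had 8 of 19 lower and Acox2 and Nr0b2 higher, against 6 and 3 without the immune lists, with a median of -0.48 (-1.65 to 0.21), or -0.58 relative to all genes. Akr1c6, a hydroxysteroid dehydrogenase, was lower by a factor of 16.1 (15.7 to 16.5). Growth hormone axis genes had 7 of 19 lower and Elovl3 higher, with a median of -0.62 (-1.57 to -0.020), or -0.72 relative to all genes.

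Metabolic lists were split at this step. Carbohydrate genes had 9 of 26 lower and Pck1, G6pc and Ppp1r3c higher, against 9 and 6 without the immune lists, with a median of -0.23 (-1.16 to 0.40), or -0.33 relative to all genes. G6pc was 20.1-fold higher (17.8 to 22.8) and Slc2a2 lower by a factor of 18.1 (16.7 to 19.6). Fatty acid oxidation had Ehhadh, Acaa1b, Hadh, Bdh1 and Fabp1 lower and Pdk4 higher among 27, against 4 and 2 without the immune lists, with a median of -0.40 (-0.80 to -0.092), or -0.50 relative to all genes. Pdk4 was 22.1-fold higher (18.1 to 27.3), and Fabp1, the main fatty acid carrier of the hepatocyte, was lower by a factor of 6.52 (6.49 to 6.55). Fatty acid synthesis and storage had Scd1, Elovl6, Fads1, Thrsp and Mlxipl lower and Plin2, Plin5 and G0s2 higher among 22, against 3 and 4 without the immune lists, with a median of -0.68 (-0.82 to 0.55), or -0.78 relative to all genes. G0s2 was 204-fold higher (154 to 276). Cholesterol genes had a median of 0.10 (-0.18 to 0.28), 0.0032 relative to all genes, which turned to -0.079 with median of ratios and -0.049 with TMM scaling, and the 1 member at least 2-fold higher, Lss, gave way to 1 lower there. Oxidative phosphorylation genes had a median of -0.21 (-0.37 to -0.085), or -0.31 relative to all genes, and mitochondrially encoded transcripts -0.42 (-0.50 to -0.21), or -0.52 relative to all genes, with no member of either at a 2-fold difference.

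Liver transcription factors had a median of 0.42 (-0.28 to 0.82), or 0.33 relative to all genes, with Klf15 and Rora higher and Nr5a2 lower among 19. The split of 2 and 1 was 2 and 2 with median of ratios or TMM scaling and 4 and 0 without the immune lists. Klf15 was 4.10-fold higher (3.86 to 4.37). Circadian clock genes had a median of 0.047 (-1.64 to 1.57), -0.051 relative to all genes, which turned to -0.14 with median of ratios and -0.11 with TMM, with Arntl, Clock, Per2 and Nfil3 higher and Nr1d2, Dbp, Tef and Bhlhe41 lower among 13. Arntl, which encodes the clock activator BMAL1, was 68.9-fold higher (50.3 to 97.1). The hour of collection is not given and may differ between these libraries. Glucocorticoid targets had a median of 0.82 (0.38 to 1.31), or 0.72 relative to all genes, at percentile 100, with Tsc22d3, Sgk1, Dusp1 and Lcn2 higher and Gadd45b lower among 12. Sgk1, a kinase of salt and glucose transport, was 9.18-fold higher (8.78 to 9.59). Heat shock and immediate early genes had a median of 0.20 (-0.42 to 0.48), or 0.10 relative to all genes, with Fos, Fosb and Dusp1 higher and Hspa1b lower among 20. Antioxidant genes had a median of -0.32 (-0.52 to 0.031), or -0.41 relative to all genes, with Hmox1 and Cat lower among 16, and Hmox1 was lower by a factor of 9.82 (9.45 to 10.2). Iron handling genes had a median of -0.081 (-1.17 to 1.80), -0.18 relative to all genes, which turned to 0.041 without the immune lists, with Tfrc and Hfe2 higher and Hamp2 and Tmprss6 lower among 11. Tfrc, the transferrin receptor, was 4.72-fold higher (4.33 to 5.14). Cell cycle genes had 4 measured members and a median of -1.65, or -1.75 relative to all genes, with Ccnd1, Gadd45a and Gadd45b lower, and 0.00022 with no minimum level.

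**Figure D2:**
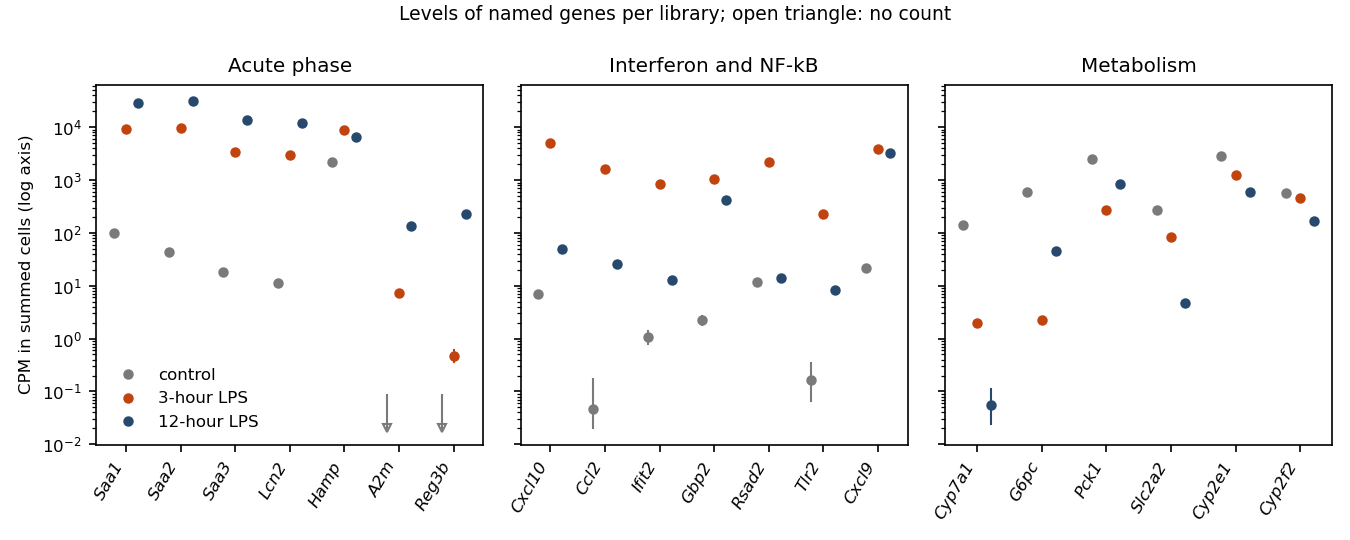
CPM on a log axis in the summed cells of the control, 3-hour and 12-hour libraries for acute phase and secreted, interferon and NF-kB, and metabolic genes; points are levels, bars exact Poisson 95% intervals that cover counting error only, and an open triangle at the foot of the axis marks a gene with no count. Cxcl10 stands at 7.13, 5136 and 50.2 CPM, and Cyp7a1 at 144, 1.98 and 0.0554 CPM.

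After each cell was thinned to 1000 UMIs, 0.603% of control cells held a Cxcl10 UMI (0.363% to 0.939%), 99.1% of 3-hour cells and 4.93% of 12-hour cells. For Saa1 the shares were 7.74%, 99.8% and 100%, and before thinning 49.2%, 100% and 100%. A Cyp7a1 UMI was found in 10.1%, 0.211% and 0% of cells, where 0 of 10705 cells allows a share of thinned cells with a UMI of up to 0.0280% at the level of 3 counts, and before thinning in 56.8%, 2.26% and 0.0747%. Hamp was found in 79.3%, 98.96% and 97.1% of cells, and Alb in 100%, 100% and 100.0%. Casp4 was found in 0.0317%, 0.298% and 0.131% of cells, near the level of single UMIs. Glul was found in 15.3%, 31.3% and 10.9% of cells, and in 72.4%, 95.8% and 64.3% before thinning. No cell class that should lack these genes was named, so the opposite zone gives the only gauge of background used here, and only for the zonal genes. The shares for Cxcl10, Saa1, Hamp, Alb and Casp4 have no background share beside them and do not separate expression from free RNA. In the periportal tercile Cyp7a1 was found in 1.90%, 0.0576% and 0% of thinned cells, Cyp2e1 in 47.0%, 28.8% and 14.5%, and Glul in 10.8%, 26.9% and 7.31%, while Cyp2f2 in the pericentral tercile was found in 8.47%, 9.22% and 5.49%. Median depths were 10112 and 16531 UMIs in the periportal and pericentral terciles of control, 11340 and 11461 at 3 hours, and 13737 and 12671 at 12 hours. Before thinning Cxcl10 was found in 5.14%, 100% and 34.2% of cells, Hamp in 99.9%, 100% and 100%, Casp4 in 0.222%, 3.25% and 1.76%, Cyp2e1 in 98.0%, 94.3% and 83.5%, and Cyp2f2 in 82.1%, 74.5% and 64.0%.

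Liver zonation, the gradient of hepatocyte functions from the portal to the central vein, was seen in each library. Across cells thinned to 1000 UMIs, the Spearman correlation of the pericentral with the periportal sum was -0.69 in control (-0.71 to -0.67), -0.43 at 3 hours (-0.45 to -0.41) and -0.44 at 12 hours (-0.46 to -0.43). Cells are not replicates, and these values describe single libraries. The mean pericentral sum per cell was 14.4, 10.2 and 3.15 UMIs and the mean periportal sum 31.6, 25.7 and 20.5 UMIs, so the correlations rest on different numbers of UMIs. Cyp3a11, a drug-metabolising cytochrome, gave 31.1%, 30.7% and 24.8% of the pericentral sum, and Serpina1e, an antitrypsin gene whose reads can be shared with its copies, gave 25.1%, 41.3% and 39.9% of the periportal sum. Without both genes the correlations were -0.67, -0.51 and -0.37, so the order of the LPS libraries depended on them, while control kept the strongest one.

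Terciles of cells were set from the difference of these sums. Each is a range of a score and not a cell type, and 407 and 130 control cells lay near the lower and upper limits, 1122 and 774 at 3 hours and 934 and 640 at 12 hours. The pericentral tercile of control had more mitochondrial UMIs than the periportal tercile (median 17.5% against 9.90%). The order was opposite at 3 hours (8.29% against 10.9%) and at 12 hours (6.41% against 8.23%). Differences between terciles are thus not separated from differences in mitochondrial share. They were not recomputed without cells of low mitochondrial share. Pericentral genes differed between these terciles by construction, with median log2 ratios of 2.87, 1.87 and 2.39, and periportal genes with -1.41, -1.24 and -1.11. Interferon-stimulated genes had medians of -0.074 in control, -0.058 at 3 hours and 0.14 at 12 hours, and 1 of 19 members in control (Ifi27, lower in the pericentral tercile), 0 of 46 at 3 hours and 0 of 40 at 12 hours differed by 2-fold. NF-kB targets were at 0.030, 0.086 and 0.097, with 1 of 15 members at least 2-fold lower in control (Cxcl9). MHC class I genes were at -0.36, -0.057 and -0.015, with 2 of 13 lower in control (Psmb8 and Psmb10). No member of these 2 lists differed by 2-fold at 3 or 12 hours. Acute phase genes had a median of -0.64 in control, with 6 of 28 members at least 2-fold lower in the pericentral tercile, against -0.11 at 3 hours and 0.016 at 12 hours with no such member. Saa2 had a log2 ratio of -2.72 in control, -0.25 at 3 hours and -0.12 at 12 hours, and Saa1 -1.45, -0.22 and -0.089. Hamp stood at -0.85, 0.48 and 0.15, and Hamp2 at -0.27, 1.05 and 1.21. Among pericentral genes, Cyp2e1 had log2 ratios of 3.06, 2.72 and 2.88, Oat, an ornithine aminotransferase, 2.94, 2.66 and 3.20, Slc1a2, a glutamate transporter, 5.22, 3.73 and 3.36, and Glul 3.06, 0.77 and 1.57. Cyp2f2 had -3.47, -2.99 and -2.55.

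**Figure D3:**
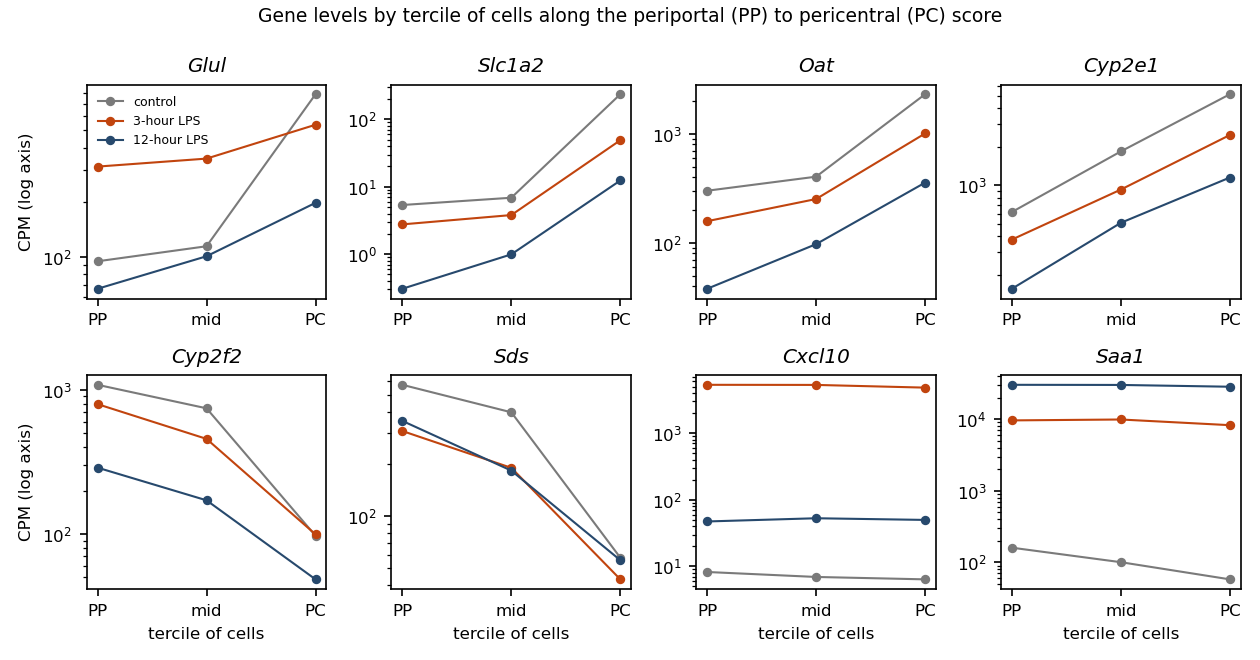
CPM on a log axis of 8 genes in the periportal (PP), middle and pericentral (PC) terciles of cells of each library; points are levels in the summed cells of a tercile and lines join the terciles of 1 library. Glul has a log2 ratio of the pericentral over the periportal tercile of 3.06 in control, 0.77 at 3 hours and 1.57 at 12 hours, and Saa1 -1.45, -0.22 and -0.089.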

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

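The criterion for these results, opposite directions in the 2 LPS libraries, was chosen after the data were seen, whereas the tests of Glul were written before their results were seen. Against control, 16 of the genes named in the text had ratios on opposite sides of 1 at 3 and 12 hours, beyond the counting interval with the total, median of ratios and TMM scaling. The difference between the times was not tested, and each time is 1 library. As log2 ratios, Arntl stood at -2.24 at 3 hours and 1.88 at 12 hours. Cldn1 stood at -2.10 and 1.92, Pdk4 at -2.78 and 0.60, Tfrc at -0.82 and 1.22, and Stab2 at -0.65 and 0.95. Acox2 stood at -0.67 and 0.61, Arg1 at -1.16 and 0.37, Clock at -1.29 and 0.28, Elovl3 at -1.38 and 0.16, and Lss at -0.69 and 0.33. In the other direction, F3 stood at 2.70 and -0.91, Gadd45b at 1.51 and -1.66, Serpina6 at 0.89 and -1.78, Fabp1 at 0.32 and -2.39, and Elovl6 at 0.12 and -1.90. Glul stood at 0.081 and -1.64, and the first of these values lay below 0 under 3 alternatives.

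Glul UMIs were found in more cells at 3 hours than in control after thinning, by a factor of 2.05, although its summed level was nearly equal, and the median and 99th percentile per cell were 4 and 24 UMIs against 1 and 134. A difference in depth per cell is argued against by that thinned ratio, since equal depth would leave it near 1. Free RNA spread over droplets would give Glul and Slc1a2 like levels in periportal cells relative to the library, but Glul's relative level of 0.784 was 5.30 times that of Slc1a2 (0.148), and Oat, Cyp2e1 and Cyp1a2 lay at 0.331, 0.297 and 0.335. Rhbg, at 5.91 CPM in the 3-hour library, went from 0.204 to 0.543, closer to Glul. A wider spread of Glul over the lobule after priming and LPS is a hypothesis that was not tested here and that staining of liver sections would test. Free RNA and differences between cell preparations stay open.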

How the results depend on the processing

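The alternatives without the 3 immune lists, without cells of low mitochondrial share, without finer clusters of endothelial or blood cell markers (monocyte markers counted or not), without the control cells led by interferon-stimulated genes, with members with no count set to 3 counts, and at the finer clustering resolution were tests chosen after the data were seen. No paired analysis was possible because each group is 1 library and all carry replicate number 1. Over the 14 alternatives that changed a value, 1135 list medians stayed within the interval of the reported value, 39 moved beyond it and 2 reversed. For genes 1029 values stayed, 758 moved and 7 reversed, without the alternative of no minimum level, which applies to lists only. The gene intervals cover counting error only and are narrow. A value whose interval held 0 was not counted as reversed when its sign turned, and lists too short for an interval were held against the range of their members. Left out of these totals are cell filters, all kept cells and joint clusters, which changed no cell and so say nothing of stability. Also left out are the removal of called doublets, since the calls were not relied on, and members with no count set to 3 counts, which moved no median. The cause of a moved value was not tested, except that another scaling moves all genes by 1 factor.

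For 3 hours against control, median of ratios scaling gave medians of -0.056 for drug metabolism, -0.45 for fatty acid oxidation, -0.55 for the urea cycle, -0.27 for pericentral genes, -0.38 for mitochondrially encoded transcripts and, reversed, 0.13 for oxidative phosphorylation. TMM gave -0.027, -0.42, -0.52, -0.24, -0.35 and 0.16 for these, and -0.49 for bile acid genes. The total without the immune lists gave -0.21 for drug metabolism, -0.60 for fatty acid oxidation, -0.70 for the urea cycle, -0.53 for mitochondrially encoded transcripts and -0.024 for oxidative phosphorylation. Mitochondrially encoded transcripts were at -0.51 with equal weight of cells and at -0.51 with thinned cells, and oxidative phosphorylation at -0.082 without cells of low mitochondrial share. Glul reversed to -0.0076 with the total without mitochondrially encoded genes, -0.17 without cells of low mitochondrial share and -0.13 at the finer resolution. Cyp2f2 reversed to 0.014 with TMM and 0.069 at the finer resolution, and Alb to 0.033 with median of ratios and 0.063 with TMM.

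For 12 hours against control, mitochondrially encoded transcripts were at -0.90 with median of ratios, -0.84 with TMM, -0.81 with equal weight of cells, -0.82 with thinned cells and -0.70 without the immune lists. Liver transcription factors were at -0.38 with TMM and -0.24 without the immune lists, where fatty acid oxidation was at -0.80 and oxidative phosphorylation at -0.085. Pericentral genes were at -2.92 without cells of low mitochondrial share. For 12 against 3 hours, median of ratios and TMM gave -0.54 and -0.51 for constitutive plasma proteins, -0.87 and -0.84 for fatty acid synthesis, -0.40 and -0.37 for oxidative phosphorylation, and -0.62 and -0.58 for mitochondrially encoded transcripts. Without the immune lists, oxidative phosphorylation was at -0.047 and the unfolded protein response at 0.90.

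The zone correlations in control, at 3 and at 12 hours were -0.59, -0.35 and -0.30 with 500 UMIs per cell, -0.73, -0.49 and -0.53 with 2000, and -0.72, -0.49 and -0.40 at the finer resolution. Without cells of low mitochondrial share they were -0.74 in control and -0.40 at 12 hours. Control kept the strongest correlation in these settings, while the order of the LPS libraries differed. The share of hepatocyte-like cells was 78.4%, 82.5% and 65.6% at the finer resolution. Depth limits genes near 3 counts, such as Ccl2 with 2 UMIs in control and Cyp7a1 with 8 UMIs at 12 hours.

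Of the counts of members at least 2-fold higher or lower, those that reached 5 and moved by over 1.5 times or to 0 with another scaling were as follows. For 3 hours against control, median of ratios and TMM gave 3 and 3 lower urea cycle genes against 12 with the total, 6 and 6 fatty acid synthesis genes against 11, 8 and 8 carbohydrate genes against 13, 4 and 4 periportal genes against 9, 4 and 4 pericentral genes against 7 and 3 and 3 glucocorticoid targets against 5. They gave 8 and 9 higher unfolded protein response genes against 5, 8 and 8 cholesterol genes against 4 and 5 and 5 complement genes against 3, and TMM gave 5 higher antioxidant genes against 2. Without the immune lists, 7 urea cycle and 6 fatty acid synthesis genes were lower and 8 cholesterol genes higher. Without mitochondrially encoded genes in the total, 5 mitochondrially encoded transcripts were lower against 3. For 12 hours against control, 5 mitochondrially encoded transcripts were lower against 8 with median of ratios, with TMM and without the immune lists. Without the immune lists, 5 liver transcription factors against 9 and 3 coagulation genes against 5 were lower and 9 cholesterol genes against 5 were higher. Without mitochondrially encoded genes, 3 cholesterol genes were higher and 8 oxidative phosphorylation genes against 4 were lower. For 12 against 3 hours without the immune lists, 9 unfolded protein response genes against 4 and 6 carbohydrate genes against 3 were higher, and 3 fatty acid synthesis genes against 5 were lower. Without cells under 5% mitochondrial share, the counts that moved by over 1.5 times or to or from 0 were of 2 members or fewer in both settings.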

Other observations

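The tests of cells of low mitochondrial share, of the upper limit on the mitochondrial share and of immune transcripts taking UMIs were chosen after the result was seen; the other tests in this part were written before theirs. At 12 hours, small finer clusters stood apart by their leading genes: 135 cells (1.26%) were led by interferon-stimulated genes such as Rsad2 and Ifit1, and 174 cells (1.63%) by Cxcl2, Ccl2, Ripk2 and Cxcl10. At 3 hours, interferon-stimulated genes were higher than in the same tercile of control by medians of 4.45 in periportal, 4.57 in middle and 4.96 in pericentral cells, and acute phase genes by 2.25, 2.42 and 2.67.

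Mitochondrially encoded transcripts took a lower share of UMIs in both LPS libraries, with log2 ratios of the summed share of -0.69 and -0.98. More cells under 5% do not account for it, since such cells were 29.5% of control (27.9% to 31.1%) but 16.2% at 3 hours (15.5% to 16.9%) and 15.5% at 12 hours (14.9% to 16.2%). Among deposited cells, 32.4% of control but at most 0.893% of an LPS library lay at 18% or more, so control lay closest to the upper limit. Cells above that limit are not in the deposited tables, so its effect on the shares cannot be determined. Immune transcripts taking UMIs do not account for the whole difference, because without the 3 lists the ratios were still -0.49 and -0.61. That the ratios shrank follows by arithmetic from the larger share of these lists in the LPS libraries. Cell quality, dissociation and the treatment itself may each explain the remainder and are confounded with the groups.

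A finer cluster of 36 control cells (1.14%) was led by Rsad2, Cxcl9, Saa2 and Ifit1, with a median log2 ratio of 2.90 for interferon-stimulated genes over the other control cells, against 1.00 for MHC class I, 0.50 for acute phase genes and -0.17 for NF-kB targets. Cells of an LPS library under control barcodes are argued against by genes that were lower in those libraries. In these cells 70 genes lower at 3 hours (median -2.42) stood at -0.19 (-0.39 to -0.10). The 220 genes lower at 12 hours (median -2.67) stood at -0.20. That 0 of the 36 barcodes occurred in an LPS library adds little. Of all control barcodes only 13 occurred in the 3-hour and 11 in the 12-hour library. Droplets joined with an endothelial or blood cell are argued against by the markers of those cells, 42.4 CPM against 33.3 CPM, a ratio of 1.28 (0.797 to 1.94) from 22 UMIs. No biological explanation was tested, since the design names none within control.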
